A study of Rattus norvegicus with 6 samples.

How the data were processed

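Poly(A)-selected RNA from primary rat nucleus pulposus cells was sequenced in 6 libraries, 3 from cells given vehicle and 3 from cells given recombinant CRLF1 for 3 days. Each library was placed in its group by its title. The deposited table holds 21062 genes under Ensembl rat gene identifiers, each with a read count and an FPKM value per library, and each of these columns was matched to a sample by the sample name in its header. The name under which the table was deposited also carries the terms St and CR+St, which no label explains, so a further treatment shared by both groups is not excluded; groups are named here as in the sample labels. Counts are whole numbers that the authors deposited without normalization, per the file headers and the values. FPKM values were deposited by the authors to 2 decimals, per the file headers. They follow the counts: of the 5637 genes with over 500 counts in each library, the length implied by counts and FPKM was within 2% of that of vehicle replicate 1 in all libraries for 78.5%. HISAT2 2.2.1, Bowtie2 2.5.1 and DESeq2 1.38.3 are named in the submitters' processing notes, without a role. The genome build, the annotation, the counting tool and any use of strand in counting are not given in the sources used here, so reads shared by overlapping genes or close paralogs cannot be told apart. The rows run from the highest to the lowest ratio of r-CRLF1 to vehicle (Spearman correlation of row number with the log2 ratio of mean FPKM, -0.99), and 5200 rows hold no count.

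None of the identifiers (0 of 21062) was found in the reference gene table used here, whose Ensembl column is empty. Gene symbols, gene positions, and gene lists written in symbols were therefore not used here. Lists of matrix, protease, senescence, cell cycle, cytokine signalling and cell type genes had been fixed before the data were examined, and no result is given for any of them. The rule for named genes, also fixed then, took the largest rises and falls among genes with an adjusted p under 0.05, with all 3 libraries of one group above or all below those of the other, with a mean of at least 1 CPM, and with a gene symbol. Its clause on symbols could not be applied. The other clauses were met by 1975 rising and 2112 falling genes, and the 2 largest in each direction are named by identifier.

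Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (12378 genes, with at least 99.96% of the counts of every library), libraries were scaled with TMM, and groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest) on all 6 libraries with group as the only term. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled totals, and log2 CPM for principal components used a prior count of 2. TMM factors ran from 0.957 to 0.964 in vehicle and from 1.03 to 1.05 in r-CRLF1 libraries. Gene-model length was computed as the value that turns the deposited counts into the deposited FPKM when totals are taken over the table. It is therefore known only up to a common factor. It is also approximate, since it stayed within 2% across libraries for only 78.5% of the genes with over 500 counts in each. Shares of counts were compared with an exact permutation test over the 20 assignments of 6 libraries to 2 groups of 3.

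Alternatives were DESeq2 1.42.0 and limma 3.58.1 (voom) in place of edgeR, DESeq2's size factors or library totals alone in place of TMM, no expression filter or a filter of 1 CPM in 3 libraries, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were limma with trend on log2(FPKM + 1), counts thinned to the smallest total, a fit without the 100 most abundant genes, and removal of a smooth (lowess) trend of log2 CPM on length in each library. No pairing of the libraries by replicate number was seen, though a weak link is not excluded. Deviations from the group means correlated at 0.0033, -0.018 and -0.048 between libraries with the same number, and nothing in the labels ties a number to an animal or day. The edgeR and DESeq2 steps were tested on simulated counts for the 12378 genes of this comparison, with the means, dispersions and totals of the real libraries and 200 genes changed by known folds of 1.3, 1.5, 2 and 4, 50 of each. The changed genes were drawn among those at 3 CPM or more, and both groups shared the dispersion of each gene. Of the edgeR calls, 7 were false (4%), and of the DESeq2 calls 6 (3.47%).

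With 17087921 to 21898424 counts per library, counting error is small for abundant genes, and the number of libraries limits their precision. For scarcer genes counting error limits the precision as well. The tested genes include 598 under 1 CPM and 2953 between 1 and 10 CPM. Counting intervals and floors do not cover variation between libraries, and reads carry no molecular identifiers in the sources used here.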

Results

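Gene expression was measured by RNA sequencing in primary rat nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc. Cells received vehicle or recombinant CRLF1 (r-CRLF1) for 3 days, with 3 libraries in each group. CRLF1, cytokine receptor-like factor 1, is a secreted protein that pairs with the cytokine CLCF1 and acts on cells through the ciliary neurotrophic factor receptor. The title of the series names matrix breakdown and cell senescence in disc degeneration as its subject, and the comparison of r-CRLF1 with vehicle asks which transcripts move when the protein is added. Total counts per library were 20854556, 20438188 and 19956354 for vehicle replicates 1 to 3 and 17087921, 19121444 and 21898424 for r-CRLF1 replicates 1 to 3. Between 14257 and 14543 genes had at least 1 count in a library. Genes carry Ensembl identifiers that the sources used here do not pair with symbols, so matrix, protease, senescence and cytokine genes, the transcript of Crlf1 among them, were not analysed here by name.

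After 3 days, the transcript level of 34.6% of the tested genes differed between r-CRLF1 and vehicle cells, in both directions and mostly by small amounts. Of 12378 genes tested with edgeR's quasi-likelihood test, 2063 were higher and 2217 lower in r-CRLF1 than in vehicle cells at a Benjamini-Hochberg adjusted p under 0.05. The median absolute log2 fold change of a called gene was 0.38. The median log2 fold change was 0.35 among the genes that rose and -0.41 among those that fell. At least a 2-fold change was reached by 356 rising and 270 falling genes, and a 4-fold change by 36 rising and 36 falling genes. The 2-fold numbers were 419 and 206 with library totals alone, and 190 and 54 with limma on log2(FPKM + 1), which shrinks low genes. Of the called genes, 4183 had all 3 r-CRLF1 libraries above or all 3 below the vehicle libraries. Such separation was found in 47.3% of all tested genes, against 10% given by chance with 3 libraries against 3.

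The balance between rising and falling genes rested on the scaling of the libraries. With the TMM factors used here, 48.2% of the called genes rose. With library totals alone, 74.3% of 5517 called genes rose, because the median log2 fold change of all genes then stood at 0.12 in place of 0.00. Directions given here are relative to the median gene. Among the 8098 genes that were not called, the 95% interval of the fold change lay within 1.3-fold in either direction for 5131, within 1.5-fold for 6406 and within 2-fold for 7400. In simulated libraries of the same depths and spread, the edgeR test recovered 56% of genes changed 1.3-fold, 80% of those changed 1.5-fold and 100% of those changed 2-fold. Changes near 1.3-fold were thus often below what 3 libraries per group detect.

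**Figure D1:**
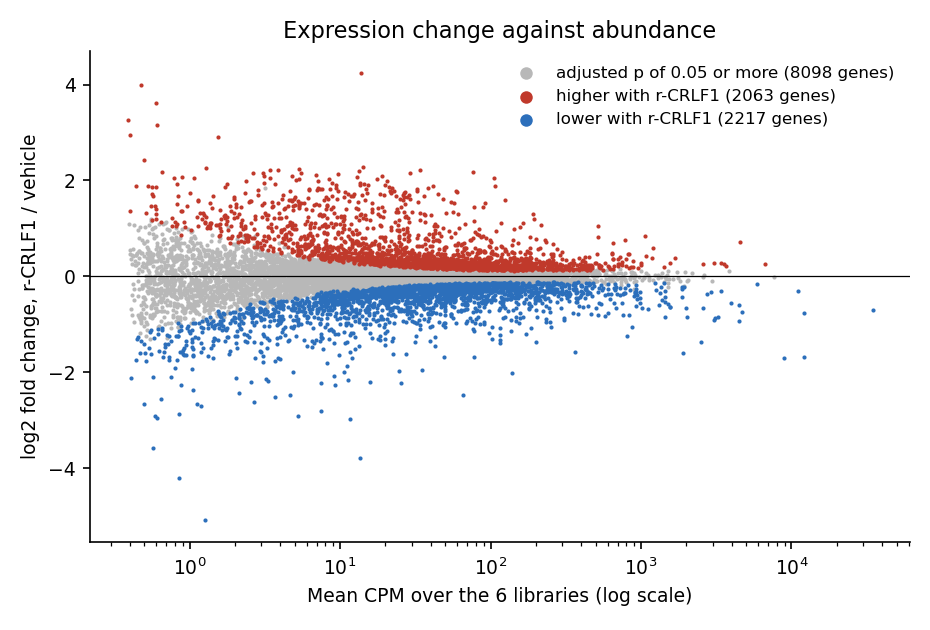
Log2 fold change of each of the 12378 tested genes (vertical axis, r-CRLF1 over vehicle) against its mean CPM (counts scaled to the TMM-adjusted library total) over the 6 libraries (horizontal log axis). Red points are the 2063 genes higher with r-CRLF1, blue points the 2217 lower, and grey points the 8098 genes not called. At the right end, above 1000 CPM, blue points outnumber red.

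The 2 largest rises and 2 largest falls, among called genes with a mean of at least 1 CPM and no overlap between the groups, all exceeded 4-fold. ENSRNOG00000020281 rose from 1.36 ± 1.82 CPM in vehicle to 26.0 ± 5.81 CPM in r-CRLF1 cells (SD, n = 3 each), a log2 fold change of 4.24 with a standard error of 0.42 (edgeR adjusted p = 2.58e-06). Its vehicle level was uneven, with 69 counts in replicate 1 against 4 and 8 in replicates 2 and 3. Without vehicle replicate 1 its log2 fold change was 6.37. ENSRNOG00000004575 rose from 0.36 ± 0.19 to 2.72 ± 0.49 CPM (SD, n = 3), a log2 fold change of 2.91 with a standard error of 0.35 (edgeR adjusted p = 1.9e-05). ENSRNOG00000025587 fell from 2.45 ± 0.40 CPM to 0.067 ± 0.059 CPM (SD, n = 3), with 52, 39 and 53 counts in vehicle and 2, 0 and 2 in r-CRLF1 libraries. Its log2 fold change was -5.09 with a standard error of 0.49 (edgeR adjusted p = 2.04e-06). ENSRNOG00000023548 fell from 25.2 ± 1.74 to 1.89 ± 1.22 CPM (SD, n = 3), a log2 fold change of -3.79 with a standard error of 0.22 (edgeR adjusted p = 2.52e-08). Its residual level was highest in r-CRLF1 replicate 1, and without that library its log2 fold change was -4.40.

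**Figure D2:**
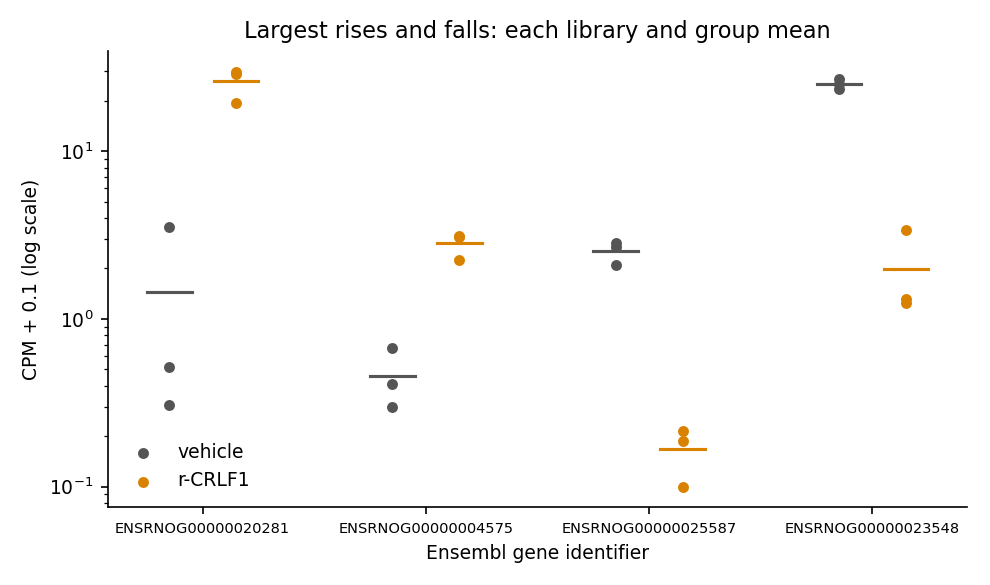
CPM plus 0.1 (vertical log axis) of the 4 named genes (horizontal axis) in each of the 6 libraries, with vehicle in grey and r-CRLF1 in orange. Points are libraries and bars are group means; in each gene the 3 r-CRLF1 libraries lie apart from the 3 vehicle libraries.

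At least 3 counts in each library of one group and none in the other group were found for 3 genes. A single gene had no count in any vehicle library and 4, 11 and 13 counts in r-CRLF1 replicates 1 to 3, which is at least 9.06-fold higher on TMM-scaled totals when the vehicle group is set at a floor of 3 counts. A pair of genes had counts in each vehicle library and none in any r-CRLF1 library. The first had 3, 3 and 3 vehicle counts, at least 3.09-fold lower in r-CRLF1, and the second had 7, 3 and 6 vehicle counts, at least 5.50-fold lower, with the floor of 3 counts taken over the r-CRLF1 group. The floor covers counting error of the group without counts, and neither that of the other group nor variation between libraries. All 3 genes were too scarce to pass the expression filter, so the main fit did not test them. They were picked after their counts were seen.

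The most abundant transcripts took a smaller share of counts in r-CRLF1 than in vehicle libraries. The 10 genes with the largest mean share of counts over the 6 libraries took up 12.6% ± 0.15 of all counts in vehicle and 8.81% ± 0.35 in r-CRLF1 libraries (SD, n = 3 each). The difference of -3.83 percentage points was far larger than the spread between libraries, and its exact two-sided permutation p of 0.1 is the smallest that 3 libraries against 3 can give. As a share of FPKM, which weights genes by length, the drop was smaller, at -1.59 percentage points. Of these 10 genes, 7 fell, 2 rose and 1 was not called by edgeR on TMM-scaled counts. The log2 fold changes that follow are also on TMM-scaled counts. They lie below the log2 ratios of the shares, which use library totals. The leading gene alone fell from 4.12% ± 0.13 to 2.73% ± 0.26 of counts (SD, n = 3). Its TMM-scaled log2 fold change was -0.71 with a standard error of 0.075. By log2 fold change, the genes ranked 3 and 5 fell most of the 10, at -1.68 and -1.71. Their shares went from 1.77% ± 0.075 to 0.60% ± 0.13 and from 1.31% ± 0.017 to 0.44% ± 0.037 of counts (SD, n = 3). The gene ranked 10 rose from 0.33% ± 0.0025 to 0.59% ± 0.017 of counts (SD, n = 3). Its TMM-scaled log2 fold change was 0.73 with a standard error of 0.053. All 5 of the leading genes were called lower by edgeR with TMM scaling and all libraries. That number was 4 with library totals alone, with DESeq2, with limma on log2(FPKM + 1), and with edgeR without vehicle replicate 1, 2 or 3, and it was 2 with a minimum log2 fold change of 1. Of the 10 genes, 5 were called lower with library totals alone, with limma on log2(FPKM + 1) and without vehicle replicate 1, 2 or 3, 6 with DESeq2 and with the replicate number as a block, and 2 with the minimum fold change. The gene ranked 4 overlapped between the groups in share, at 0.82%, 1.17% and 1.10% in r-CRLF1 replicates 1 to 3. Its vehicle shares were 1.15%, 1.18% and 1.16%. Without r-CRLF1 replicate 1, all 5 leading genes were still called lower by edgeR with TMM scaling.

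**Figure D3:**
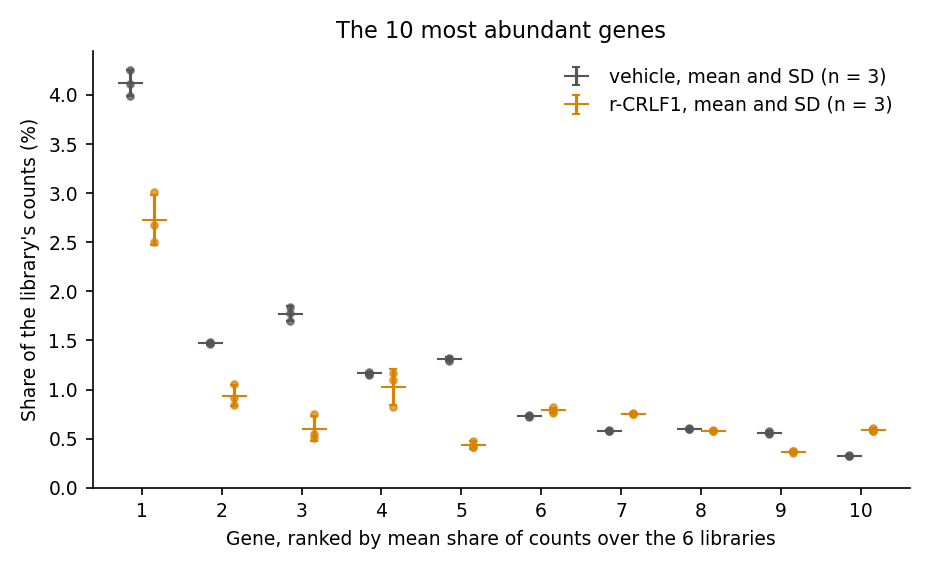
Share of each library's counts in percent (vertical axis) for the 10 most abundant genes, ranked by their mean share over the 6 libraries (horizontal axis). Points are libraries and bars give the mean and SD of 3 vehicle (grey) or 3 r-CRLF1 (orange) libraries; the leading gene drops from 4.12% to 2.73%, and the gene ranked 10 rises from 0.33% to 0.59%.

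The same direction held for the wider class of very abundant genes. Of 93 genes with a mean above 1000 CPM, 41 fell and 16 rose. With library totals alone, 30 of them fell and 27 rose. The direction of calls in this class differed from that of the other called genes (Fisher's exact test across genes, two-sided, p = 0.0021, adjusted p = 0.0021 over 2 such tests), though genes are not independent replicates. Between 100 and 1000 CPM, 442 genes rose and 455 fell of 1945. Between 10 and 100 CPM, 1175 rose and 1228 fell of 6789. Larger folds came from scarcer genes: of the genes between 1 and 10 CPM, 186 rose and 136 fell at least 2-fold, against 10 and 15 of the genes between 100 and 1000 CPM. The median absolute log2 fold change of called genes was 0.84 in the first of these classes and 0.25 in the second. A scarce gene needs a larger fold to pass the test.

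Genes with long models moved down relative to genes with short models. Length was taken from the ratio of deposited counts to deposited FPKM, and the tested genes were divided into 8 classes of equal size. In the shortest class (up to 1336 bp), 227 genes rose and 117 fell of 1548. In the longest (5206 bp and over), 233 rose and 441 fell of 1548. The number of rising genes changed little between the classes, from 227 to 278, while falling genes increased at each step. The median log2 fold change ran from 0.05 in the shortest class to -0.07 in the longest, a difference of -0.12. That difference was -0.12 with library totals alone as well, although 453 genes of the longest class then rose and 287 fell. With limma on log2(FPKM + 1) the difference was -0.10, and 325 genes of that class rose and 190 fell. With a smooth trend on length removed from each library, which takes out the difference by construction (0.0020), 354 rose and 330 fell. The direction of calls in the longest class differed from that of the other called genes (Fisher's exact test across genes, two-sided, adjusted p = 1.65e-14 over 2 such tests), though genes are not independent replicates.

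**Figure D4:**
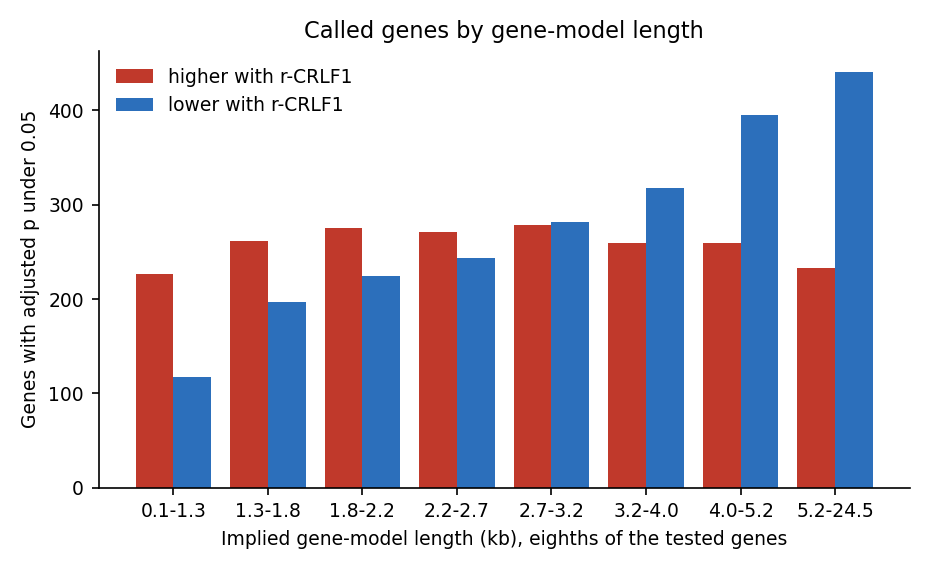
Number of genes higher (red) and lower (blue) with r-CRLF1 at an edgeR adjusted p under 0.05 (vertical axis) in 8 classes of implied gene-model length in kilobases (horizontal axis). Falling genes increase from 117 in the shortest class to 441 in the longest, while rising genes stay between 227 and 278.

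The 2 groups were far apart and differed in their own spread. The first principal component of log2 CPM held 66.9% of the variance and placed the vehicle libraries between -25.7 and -24.6 and the r-CRLF1 libraries between 19.6 and 29.3. The coefficient of variation between libraries beyond counting noise was 3.58% in vehicle and 7.33% in r-CRLF1. The chi-square per degree of freedom between pairs of libraries was 2.60 to 3.06 within vehicle, 4.93 to 17.1 within r-CRLF1 and 51.1 to 87.9 between the groups, where sampling noise alone gives 1. No pair of libraries was therefore close enough to be one library counted again. The second component, with 10.4% of the variance, separated r-CRLF1 replicate 1 (-20.7) from r-CRLF1 replicates 2 and 3 (6.95 and 10.5). Without r-CRLF1 replicate 1 the edgeR test called 4820 genes, 4031 of them called in the same direction with all libraries. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.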

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

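The alternatives fixed beforehand and those added after the data were seen (FPKM, thinning, removal of abundant genes, removal of the length trend) gave 3347 to 5517 called genes against 4280, except with a minimum log2 fold change of 1, which left 626 (356 higher, 270 lower). The share of rising calls moved by over 10 percentage points in 2 fits. Library totals alone gave 4098 higher and 1419 lower genes, a change of scaling only. limma on log2(FPKM + 1) gave 3728 higher and 1153 lower. It also changed the tool, the value scale and the genes tested (11001 against 12378). With limma-voom on TMM-scaled counts 47.9% of the calls rose, which argues against the use of limma alone as the cause. FPKM values carry no TMM factors. With them 76.4% of the calls rose, near the 74.3% of library totals alone, so a change of scaling alone moved the share by a like amount. The value scale and the FPKM filter were not varied alone, so their part was not tested. The median log2 fold change of all genes was 0.12 with library totals alone and 0.11 with limma on log2(FPKM + 1). Every one of the 1419 genes lower with totals alone was also lower with TMM. DESeq2 called 3808 genes, of which 3791 were called in the same direction by edgeR, and limma-voom called 4301. Without an expression filter 4311 genes were called and with the stricter filter 4229. The replicate block, on numbers that no label ties to an animal or day, gave 3996 called genes, and no library correlated best with its own number. Together with removal of the length trend the block gave 3946. Leaving out each library in turn gave 3347 to 4820 genes. The 4 named genes kept direction and adjusted p under 0.05 in each fit that tested them. ENSRNOG00000025587 was not tested on FPKM, and on the log2(FPKM + 1) scale, which shrinks low genes, the log2 fold changes of the others were 3.17 (ENSRNOG00000020281), 1.04 (ENSRNOG00000004575) and -1.97 (ENSRNOG00000023548). limma-voom gave 5.18 for ENSRNOG00000020281. The drop in the share of the 10 most abundant genes was -3.68 to -4.02 percentage points with each library left out and -1.59 as a share of FPKM, which weights genes by length. Tests of gene lists and of rows with symbols were not run, since no identifier has a symbol here, and the pseudocount alternative applies only without counts.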

Other observations

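The test on abundant genes, the tests of power and of RNA quality for long genes, and both tests on r-CRLF1 replicate 1 were chosen after the result was seen. The fits that thin the counts or remove the length trend were added after the data were examined, with their bounds set before their values were known.

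The number of genes called between r-CRLF1 and vehicle was set against technical origins. The labelled split called 4280 genes, and the 9 other splits of the 6 libraries into 3 and 3 called 0 with edgeR (82 to 310 genes at an unadjusted p under 0.05, against 5403 for the labelled split). Each other split has libraries of both groups on each side, so the group difference widens the spread within a side. Few calls are then likely whatever the origin of that difference. With 1 of 10 splits reaching the real count, the splits are also too few for a share under 0.05. No conclusion is drawn from them. Unequal depth is argued against, since 94.2% of the called genes stayed called in the same direction after thinning to the smallest total. So is a trend of read yield with length (92.3% stayed called with the trend removed). The drop of a few very abundant genes lifts all other genes alike when library totals alone are used, and 25.4% of the 5454 calls outside the 100 most abundant genes were still lower there, which argues against it as the whole origin of the calls. The number in each direction does depend on the scaling, and 1419 of the 2217 genes lower with TMM were lower with library totals alone. A handling difference between the groups is not recorded in the labels and stays open beside a response to r-CRLF1.

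The lower position of long genes with r-CRLF1 is not a matter of their larger read numbers, because the median log2 fold change itself differed by -0.116 between the longest and shortest classes (95% bootstrap interval -0.134 to -0.091 over 2000 draws). Nor does abundance account for it: with genes cut into 4 length and 4 abundance classes, the longest lay below the shortest in 4 of 4 abundance classes, by -0.16, -0.16, -0.12 and -0.047. The bootstrap interval is not taken as a measure of the spread between libraries. With each library left out in turn, the median of the longest eighth minus that of the shortest was -0.103 to -0.126. A difference in RNA quality or fragmentation between the groups stays open. The slope of log2 CPM on length was 0.0088 to 0.028 per doubling in vehicle and -0.025 to -0.016 in r-CRLF1 libraries. The gap between group means was 2.00 times the largest gap within a group, which a quality difference that follows the groups and a biological change predict alike, so it decides nothing between them. A candidate explanation of biological kind, a class of long transcripts lowered by r-CRLF1, cannot be told apart from it, because library quality may follow the groups and gene names were not used here.

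r-CRLF1 replicate 1 lay apart from replicates 2 and 3, and it is also the library with the lowest total. Depth is argued against: among the 2038 genes at 100 CPM or more, where counting error is small, its median absolute log2 difference to the others was 0.082 and 0.092, against 0.055 between replicates 2 and 3, a ratio of at least 1.49. A smaller response, or an admixture of vehicle-like RNA, predicts that responding genes lie nearer to vehicle in replicate 1, and it stays open. Among genes called without replicate 1, its log2 change from the vehicle mean was 0.78 of that of replicates 2 and 3 (median over genes), against 0.96 for replicate 2 and 1.06 for replicate 3 taken in the same way. On the first principal component it stood at 19.6, against 26.1 and 29.3. Its chi-square per degree of freedom to vehicle libraries was 51.1 to 54.3, against 67.1 to 87.9 for replicates 2 and 3, a measure that also grows with depth. A single library does not show whether such a shift accounts for the whole of the difference. A difference in culture or library preparation of that replicate is not recorded in the labels and was not tested.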
